A study of Homo sapiens with 3 samples.

How the data were processed

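RNA was extracted from frozen tumour tissue, polyadenylated RNA was selected with magnetic beads and libraries were built with an NEBNext kit, per the labels' protocols. The labels give 3 samples of 1 group, pediatric high-grade glioma cases 1 to 3, and each case is treated as a separate tumour with 1 library. No batch, treatment or control sample is given in the labels. GRCh37, hg19 and FastQC are named in the submitters' processing notes. The aligner, the annotation and all versions are not given in the sources used here.

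The authors deposited 1 gene table per sample in the layout of RSEM, per the file headers. Each table has 32617 rows named by gene symbol, with the Ensembl transcripts summed in each row. The deposited expected counts are estimated reads per gene before any normalisation, and 58.2% to 60.7% of them are whole numbers. The file headers name columns of TPM and FPKM values. By the definition of TPM, the authors' values are scaled so that each library sums to 1000000. The deposited FPKM values are, also by definition, a constant multiple of TPM within a library. The deposited lengths are abundance-weighted transcript lengths, and effective length was 75 bases shorter in 99.8% of rows. Because rows are joined by symbol, genes that share a symbol share a row, and reads shared by near-identical genes were divided by the authors' estimation. Nothing states whether strand was used, so genes that overlap on opposite strands cannot be told apart.

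Levels within a library are given in TPM. Ratios between libraries were computed from the expected counts divided by library total and TMM factor (edgeR 4.0.16 in R 4.3.3, on counts rounded to whole numbers), with 0.5 added for log2 ratios of lists. The TMM factors were 0.990, 0.997 and 1.01. For ratios of single genes a count under 3 was set to 3 per library, so that such a ratio is a lower limit where the count is 0. Intervals on counts are exact Poisson intervals at 95%, and intervals on ratios are exact conditional binomial intervals. They cover counting error only, not differences between pieces of a tumour. As a 1-sided 95% limit a count of 0 allows up to 3 counts, or 0.0631, 0.0983 and 0.0903 CPM in cases 1, 2 and 3. The 2-sided interval of a count of 0 ends at 3.69 counts, so an interval on a ratio can start below the ratio at 3 counts. Gene types came from GENCODE release 29 by transcript identifier, which matched 31490 rows, of which 19294 are protein-coding. That release is on GRCh38, whereas the submitters name GRCh37, so it was used for gene types, for names and for the position of the target genes alone.

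With 1 library per case no gene was tested between cases and no p-value is given for such a difference. The target receptor was compared with the other receptor tyrosine kinases within libraries by an exact sign-flip permutation test over the 3 cases (8 sign patterns). Gene lists were compared between cases by their median log2 ratio, placed among 10000 random lists in which each member was replaced by a gene within 100 ranks of its mean expression. The 28 lists, the comparisons, the alternatives and the rule for named genes were fixed before the data were examined. The rule names PDGFRA, KIT, the ligands and neighbours of PDGFRA, the 5 receptors with the highest mean and the 3 with the widest range, the 3 highest and 2 widest members of every other list, and for each case the 5 protein-coding genes highest and the 5 lowest against both other cases at 100 counts or more. The 10 genes with the highest mean TPM could also be named. Of 334 list members 331 were measured, 3 of them under an older symbol (C1orf192 for CFAP126, CXorf67 for EZHIP and IGJ for JCHAIN), and 3 had no matching row (NEFL, CD24 and PECAM1). A few genes that the rule names are not reported here. Genes that can reveal the sex or inherited genotype of a person were never named.

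The list and ratio steps were tested on data simulated from the mean profile of the 3 libraries at their real depths. The simulated libraries were scaled by their totals alone, so the TMM step was not tested. Single genes were counted only where the mean profile gave at least 50 counts at the smallest depth. In the simulated comparison of case 3 with case 1 over 32617 rows, 100 of 100 genes changed 8-fold passed the 4-fold limit, as did 0 of 100 genes changed 2-fold and 0 of 16204 unchanged genes. Over the same simulated libraries, the lists changed 4-fold in case 3 stood apart in 4 of 4 combinations with case 3, and 1 of 78 combinations of the other lists stood apart. The simulation held counting noise alone. Alternatives were DESeq2 1.42.0 size factors, library totals, TPM, FPKM, other pseudocounts and count limits, protein-coding genes alone, unmatched random lists and leaving out each case. Further scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.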

Results

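RNA from frozen tumour tissue of 3 pediatric high-grade gliomas was profiled by sequencing of polyadenylated RNA, with 1 library per case. The series concerns avapritinib, a kinase inhibitor of PDGFRA and KIT, in diffuse midline glioma, a tumour of midline brain structures that carries an altered histone H3. The labels of the 3 samples give no histone status, no PDGFRA status and no treatment, and there is no control tissue. The cases therefore form 1 group of 3 tumours, and the data answer at what level the target receptors were expressed and how far the tumours differed from each other. Library totals in units of 1000000 expected counts were 47.5 in case 1, 30.5 in case 2 and 33.2 in case 3. At least 10 counts were assigned to 20779, 19352 and 20509 of the 32617 gene rows in cases 1, 2 and 3. Mitochondrially encoded genes took 5.07%, 6.32% and 6.71% of the counts. Across genes, the Spearman correlation of log2(TPM + 1) was 0.949 between cases 1 and 2, 0.910 between cases 1 and 3 and 0.898 between cases 2 and 3. Each pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 269, 502 and 523, which a single library deposited more than once would not give.

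PDGFRA, the receptor for platelet-derived growth factors that marks oligodendrocyte precursor cells, was abundant in cases 1 and 2 and scarce in case 3. Its level was 221 TPM in case 1, 238 TPM in case 2 and 1.58 TPM in case 3, with a mean of 153 ± 132 TPM (SD, n = 3). Without case 3 the mean was 229 TPM. These values rested on 36978, 26224 and 140 counts, and the 95% exact Poisson interval of the count in case 3 was 118 to 165. After TMM normalisation PDGFRA was 189-fold higher in case 1 than in case 3 (95% counting interval 160 to 225) and 208-fold higher in case 2 than in case 3 (176 to 247). Cases 1 and 2 differed little, at a ratio of 0.911 (0.896 to 0.925). KIT, the stem cell factor receptor and the other target named above, lay at 5.26, 9.90 and 7.64 TPM, a mean of 7.60 ± 2.32 TPM (SD, n = 3). With 1 library per case, no test of one case against another could be made, and all intervals on counts cover counting error only. In the GENCODE annotation of GRCh38, PDGFRA is a protein-coding gene on chromosome 4 from 54229097 to 54298247, and KIT lies on the same chromosome from 54657918 to 54740715. The deposited tables carry no coordinates, and values are summed over all transcripts of a gene.

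The ligands of the receptor were lowest in case 3. PDGFA measured 104, 44.9 and 18.6 TPM in cases 1, 2 and 3, PDGFC 31.9, 21.3 and 5.86 TPM, and PDGFB 9.74, 8.29 and 5.09 TPM. All 4 ligand genes were lowest in case 3 and highest in case 1. The median ratio was 4.51-fold between cases 1 and 3, at percentile 0.32 of 10000 random lists matched on expression. It was 2.56-fold between cases 2 and 3, at percentile 2.13, and that difference no longer stood apart with DESeq2 size factors, with TPM or with a pseudocount of 0.1 or 2. The 12 genes around PDGFRA on 4q12, PDGFRA and KIT included, did not stand apart in any pair of cases. Among them LNX1 measured 11.4, 28.0 and 3.97 TPM and FIP1L1 74.1, 87.2 and 39.0 TPM, against 64.5, 43.9 and 52.7 TPM for TMEM165.

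The target receptor was next compared with the other 57 receptor tyrosine kinases in the same libraries. By TPM, PDGFRA took rank 3 of 58 in case 1, rank 2 in case 2 and rank 44 in case 3. KIT took ranks 40, 24 and 23. The collagen receptor DDR1 held a near-constant level of 291 ± 9.62 TPM (SD, n = 3) and was the only receptor above PDGFRA in all 3 cases. The neurotrophin receptor NTRK2 measured 120, 135 and 450 TPM and led in case 3. The hepatocyte growth factor receptor MET reached 442 TPM in case 1, the highest of all receptors there, and 0.52 and 0.19 TPM in cases 2 and 3. RET, a receptor for glial-derived neurotrophic factors, measured 67.5, 6.32 and 2.53 TPM. FGFR1 measured 104, 46.7 and 40.5 TPM, and TYRO3 52.2, 38.7 and 69.8 TPM. CSF1R, the colony-stimulating factor receptor of microglia, measured 165, 21.2 and 50.6 TPM. As a list, the 58 receptors were lower in case 3, by a median of 1.65-fold against case 1 (41 of 58 lower) and 1.34-fold against case 2 (40 of 58 lower).

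Of the 57 other receptors, 55 lay below PDGFRA in case 1, 56 in case 2 and 14 in case 3, and 13 did so in every case. Without case 3, 55 receptors lay below PDGFRA in both remaining cases. The exact two-sided sign-flip permutation test over 3 cases cannot give a p below 0.25. The 14 receptors with the same direction in every case were at that limit, so none could be called different from PDGFRA.

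**Figure D1:**
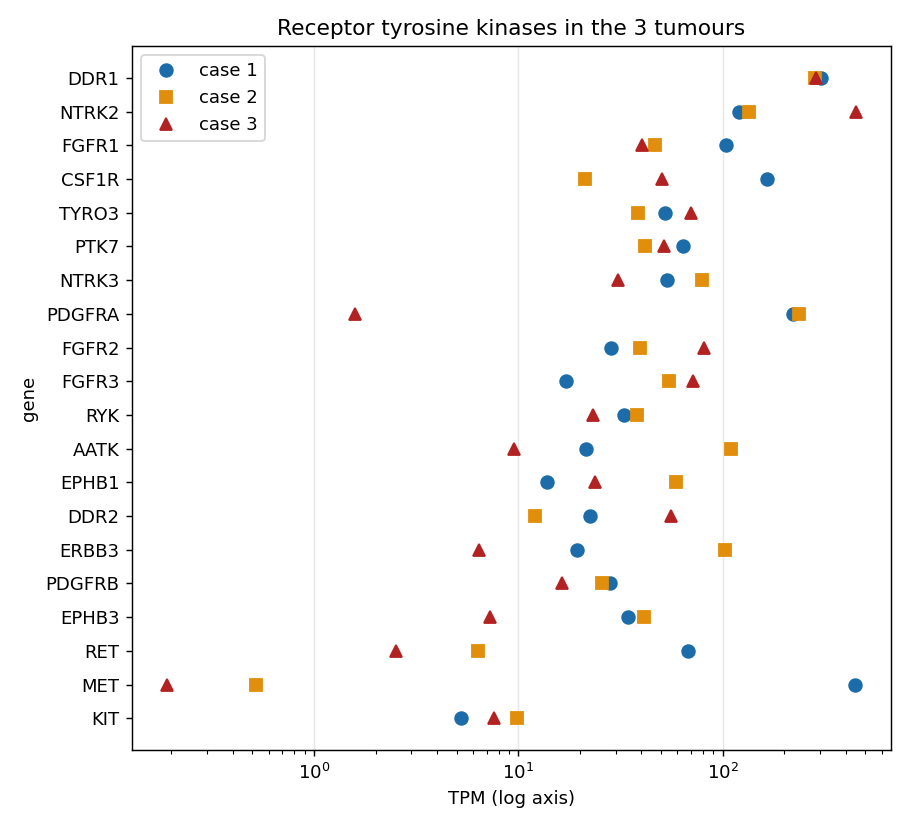
TPM on a log axis for 20 receptor tyrosine kinases in case 1 (circles), case 2 (squares) and case 3 (triangles), 1 point per library: the 17 with the highest mean log2(TPM + 1), followed by RET, MET and KIT. PDGFRA lies at 221 and 238 TPM in cases 1 and 2 and at 1.58 TPM in case 3, while MET lies at 442 TPM in case 1 alone.

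To describe how the tumours differed, 28 gene lists fixed before the data were examined were compared between each pair of cases. The median log2 ratio of a list was placed among 10000 random lists of the same size matched on mean expression, and a list stood apart where it lay among the lowest or the highest 2.5% of them. This held for 48 of 84 combinations of list and pair, where 4.20 would be expected of random lists. The percentiles describe these 3 libraries and are not p-values, and members of a list that vary together stand apart more readily than random genes. Ratios are of TMM-normalised CPM with 0.5 added. The median gene differed by 0.12 on the log2 scale between cases 1 and 3, and by 0.02 and 0.04 in the other pairs. With TPM in place of normalised counts these shifts were 0.20, 0.07 and 0.07.

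Genes that report signalling through the MAPK pathway were lowest in case 3. All 12 were lower there than in both other cases, with a median ratio of 8.06-fold against case 1 and 3.54-fold against case 2. Both medians lay beyond every random list. Cyclin D1 (CCND1), which drives entry into the cell cycle, measured 194, 264 and 18.9 TPM. The transcription factor ETV1 measured 111, 178 and 10.9 TPM, and PHLDA1 163, 169 and 8.73 TPM. The feedback inhibitors DUSP4 and SPRY1 were highest in case 1, at 36.9 and 65.3 TPM, against 3.60 and 9.04 TPM in case 2 and 0.06 and 1.76 TPM in case 3. Between cases 1 and 2, 9 of the 12 were higher in case 1, with a median ratio of 1.95-fold.

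Proliferation genes were low in case 3. All 20 were lower there than in each other case, by a median of 5.93-fold against case 1 and 9.83-fold against case 2, beyond every random list. TOP2A, the topoisomerase of dividing cells, measured 92.4, 170 and 2.59 TPM, and the mitotic kinase AURKB 37.3, 61.2 and 0.81 TPM. The members with the highest mean level were MCM3, with 63.4, 64.5 and 22.8 TPM, TYMS, with 48.4, 134 and 26.6 TPM, and PCNA, with 90.1, 73.6 and 63.4 TPM. Case 2 exceeded case 1 for 19 of the 20, by a median of 1.53-fold.

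Oligodendrocyte precursor genes were also lowest in case 3. All 14 were lower in case 3, by a median of 11.9-fold against case 1 and 16.1-fold against case 2, and 11 of 14 were higher in case 2 than in case 1. The lineage factor OLIG1 measured 579, 1247 and 24.9 TPM, SOX10 186, 628 and 5.88 TPM, and GPR17, a receptor of committed precursors, 25.4, 275 and 1.48 TPM. The matrix protein BCAN and the phosphatase PTPRZ1 measured 592, 1504 and 286 TPM and 630, 502 and 228 TPM. The neuroblast list was lower in case 3 by a median of 9.82-fold against case 1, with 7 of 9 members lower, and 4.81-fold against case 2, with 8 of 9 lower. The median log2 ratio of case 2 over case 3 was 2.27, and lay at 0.97 with a pseudocount of 2, 3.82 with 0.1 and 3.88 with only members of at least 10 counts in a case, where that of case 1 over case 3 was 4.35 against 3.30. DCX, a microtubule protein of migrating neurons, measured 36.2, 64.3 and 0.49 TPM, SOX4 84.2, 330 and 7.98 TPM, ELAVL4 90.8, 51.2 and 2.67 TPM and TUBB3 238, 253 and 119 TPM.

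Ependymal genes and astrocyte genes were highest in case 3. All 8 ependymal genes, which serve motile cilia, were higher in case 3 than in each other case, by a median of 41.8-fold against case 1 and 58.9-fold against case 2. For case 2 over case 3 the median log2 ratio of -5.88 became -6.48 in TPM and -5.19 with a pseudocount of 2. TPPP3 measured 37.6, 67.6 and 2152 TPM, RSPH1, a protein of the ciliary radial spoke, 4.04, 3.42 and 526 TPM, and C1orf192, now named CFAP126, 5.71, 3.70 and 677 TPM. FOXJ1, the regulator of motile cilium formation, measured 1.51, 2.08 and 259 TPM and was named after its values were seen. Among 12 astrocyte genes, 10 were higher in case 3 than in case 1 and 11 higher than in case 2, by medians of 3.41-fold and 7.12-fold. The intermediate filament GFAP measured 11062, 5316 and 16819 TPM. Clusterin (CLU) measured 6847, 878 and 24579 TPM, and the gap junction protein GJA1 54.0, 63.2 and 1132 TPM. The lipid carrier APOE was highest in case 1, at 2416 TPM, against 756 TPM in case 2 and 1564 TPM in case 3.

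**Figure D2:**
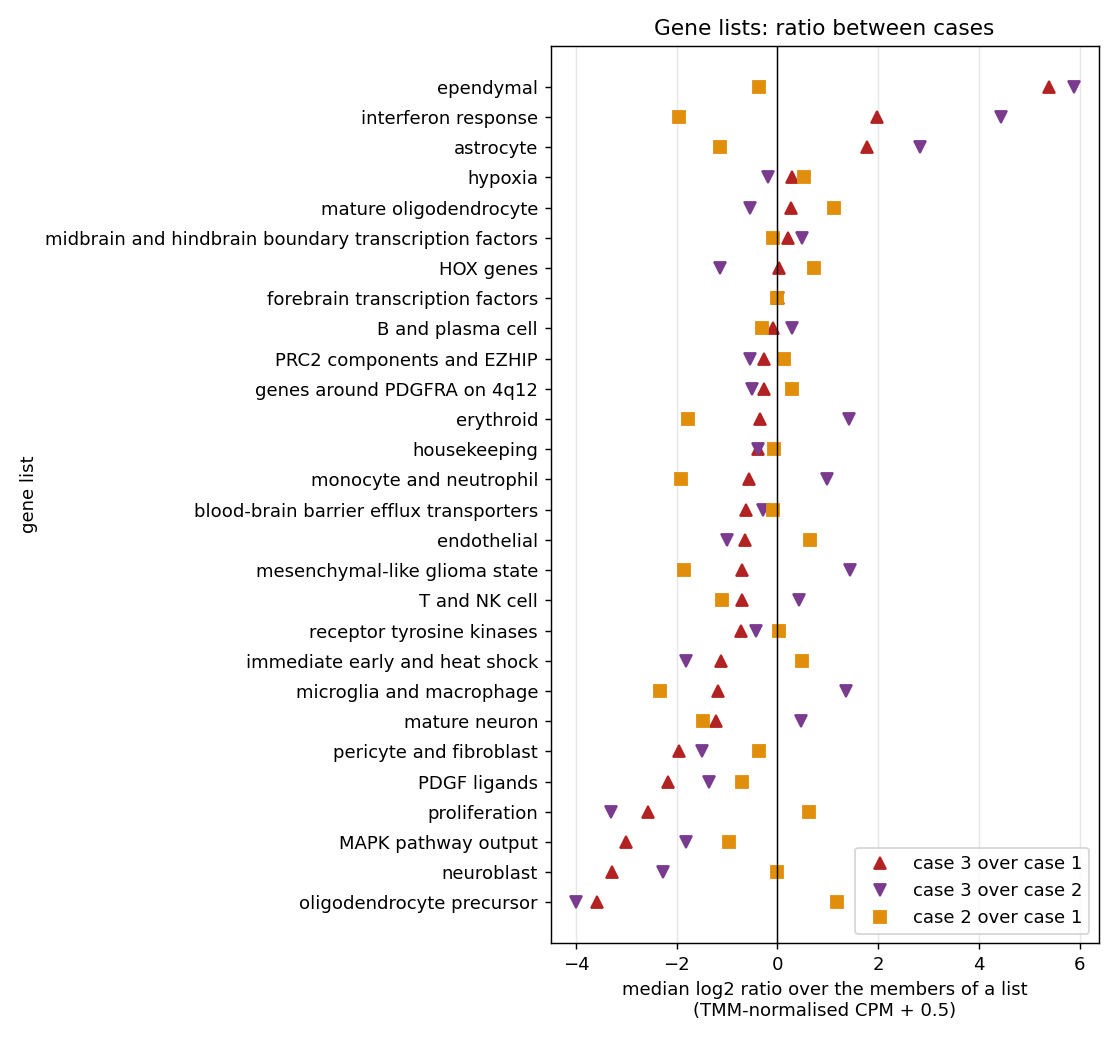
Median log2 ratio of TMM-normalised CPM + 0.5 over the members of each of the 28 gene lists, for case 3 over case 1, case 3 over case 2 and case 2 over case 1, with 1 library per case and the zero line drawn. The ependymal list lies at 5.39 and 5.88 in case 3 over cases 1 and 2, and the oligodendrocyte precursor list at -3.58 and -4.01.

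Genes of mature oligodendrocytes did not move as one group. The myelin gene CNP was highest in case 2, at 141, 737 and 162 TPM. MBP was highest in case 3, at 487, 1081 and 1787 TPM. The later myelin genes MOBP and ERMN were lowest in case 2, with 68.4, 2.61 and 172 TPM and 32.6, 0.53 and 37.1 TPM. The list stood apart only in case 2 over case 1, with a median of 2.19-fold and 8 of 12 members higher. Mature neuron genes were highest in case 1, by a median of 2.77-fold against case 2 and 2.34-fold against case 3. In each comparison 10 of 11 were higher in case 1, and 9 of 11 were highest there of the 3 cases. STMN2, a microtubule regulator of neurons, measured 237, 111 and 32.9 TPM, the synaptic protein SNAP25 83.2, 28.8 and 45.0 TPM, and the GABA-synthesising enzyme GAD1 57.5, 0.12 and 2.93 TPM.

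Microglia and macrophage genes were highest in case 1 and lowest in case 2. The 3 chains of complement C1q shared this order, with 382, 36.1 and 139 TPM for C1QA, 533, 56.8 and 194 TPM for C1QB and 571, 76.0 and 223 TPM for C1QC. The scavenger receptor CD163 measured 25.4, 1.12 and 5.90 TPM. The median ratio was 5.06-fold between cases 1 and 2, with 13 of 14 genes higher in case 1 and MRC1, named after its values were seen, at 0 in both, and 2.27-fold between cases 1 and 3, with 12 of 14 higher in case 1. The mesenchymal-like list, which includes genes that macrophages also express, was lowest in case 2 for all 12 members. Its median was 3.60-fold lower than in case 1 and 2.72-fold lower than in case 3. CHI3L1 measured 1405, 6.48 and 191.9 TPM and VIM 2877, 569 and 3762 TPM, while ANXA1 and S100A10 were highest in case 3, at 416 and 1260 TPM. T and NK cell genes were low, with a median of 3.06, 0.96 and 1.39 TPM, and all 9 were higher in case 1 than in case 2. B and plasma cell genes stood apart in no pair, at medians of 0.53, 0.23 and 0.52 TPM.

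The erythroid list was 3.41-fold higher in case 1 than in case 2 for 6 of 6 members, and 2.68-fold higher in case 3 than in case 2 for 4 of 6. With only members of at least 10 counts in a case, the median log2 ratio was 3.13 for case 1 over case 2, against 1.77 with all members, and -2.76 for case 2 over case 3, against -1.42. The haemoglobin genes HBB and HBA2 measured 315, 30.3 and 205 TPM and 285, 27.2 and 225 TPM, although reads of HBA2 and its near-identical copy HBA1 cannot be told apart with certainty. The monocyte and neutrophil list was 3.75-fold higher in case 1 than in case 2, with 5 of 7 members higher and a median log2 ratio of 1.91, or 1.05 with a pseudocount of 2. It had LYZ at 27.8, 4.73 and 14.1 TPM and CSF3R at 31.0, 6.17 and 21.4 TPM. The endothelial list had a median ratio 1.56-fold higher in case 2 than in case 1, with 6 of 10 members higher and 4 lower, and 2.01-fold higher in case 2 than in case 3, with 9 of 10 higher, with CLDN5 at 38.8, 78.8 and 29.8 TPM and VWF at 24.3, 19.1 and 8.03 TPM. When case 1 was left out, the endothelial difference between cases 2 and 3 had a median log2 ratio of 1.01 and no longer stood apart. Pericyte and fibroblast genes were 3.88-fold and 2.82-fold lower in case 3 than in cases 1 and 2, with DCN at 75.6, 42.4 and 12.6 TPM and MCAM at 94.3, 71.2 and 17.3 TPM.

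Interferon-induced genes were highest in case 3 and lowest in case 2 for all 11 members. The median ratio was 3.96-fold for case 3 over case 1, 21.7-fold for case 3 over case 2 and 3.85-fold for case 1 over case 2, all beyond every random list. IFI6 measured 471, 176 and 1447 TPM, the ubiquitin-like protein ISG15 131, 85.9 and 525 TPM, and IFI44L 63.1, 7.34 and 265 TPM. OAS1, a sensor of double-stranded RNA, measured 73.0, 3.60 and 184 TPM. The list of immediate early and heat shock genes was highest in case 2, by medians of 1.40-fold against case 1 (10 of 12 members higher) and 3.52-fold against case 3 (9 of 12 higher), with 234, 1827 and 91.1 TPM for FOS and 101, 686 and 23.2 TPM for EGR1, while the heat shock gene HSPA1A, which shares reads with its near-identical copy HSPA1B, measured 103, 123 and 286 TPM. Hypoxia genes stood apart only in case 2 over case 1, at a median of 1.44-fold that did not stand apart with a pseudocount of 2, with LDHA at 140, 253 and 175 TPM, although NDRG1 was lowest in case 2, at 178, 30.4 and 110 TPM.

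**Figure D3:**
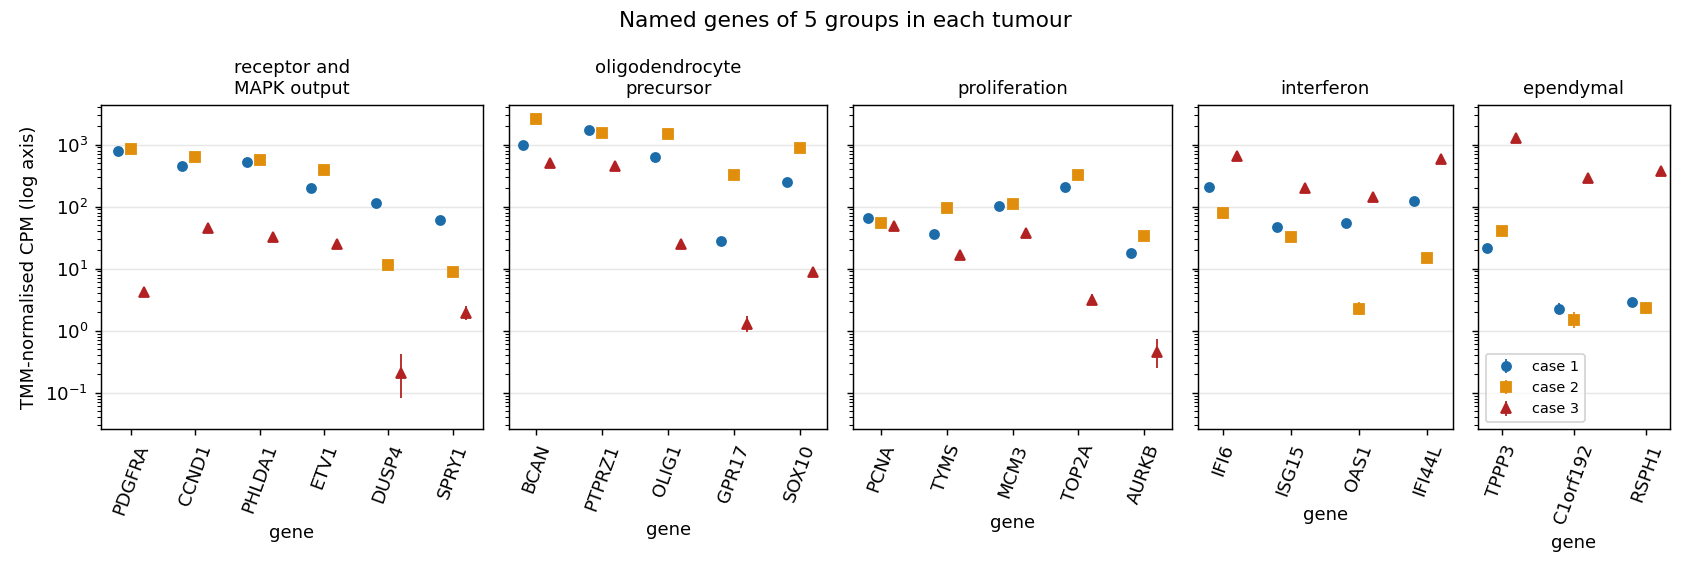
TMM-normalised CPM on a log axis for PDGFRA and named genes of the MAPK output, oligodendrocyte precursor, proliferation, interferon and ependymal lists, with 1 point per library and 95% exact Poisson intervals of the counts as bars. Case 3 (triangles) lies lowest for every gene of the first 3 panels and highest for every gene of the last 2.

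Among transcription factors that mark position along the brain axis, the HOX list set case 2 apart from both other cases, and none of the 3 lists of this kind stood apart between cases 1 and 3. HOX genes, which mark hindbrain and spinal cord, were higher in case 2 by a median of 1.66-fold against case 1 (14 of 20 higher) and 2.20-fold against case 3 (12 of 20 higher). The latter is a log2 ratio of 1.14, and 2.15 with only members of at least 10 counts in a case. HOXA3 measured 7.81, 26.8 and 0.15 TPM, HOXD3 19.5, 21.2 and 0.77 TPM and HOXC4 1.69, 22.0 and 7.87 TPM. HOXA7 lay at 42.0 TPM in case 2, 0.13 TPM in case 1 and 0.05 TPM in case 3. LHX2, a member of the forebrain list, measured 67.1 TPM in case 2 against 0.12 and 0.49 TPM. EN1, a factor of the midbrain and hindbrain boundary, had 377 counts in case 3 and none in case 2. With counts under 3 set to 3, EN1 was 176-fold higher in case 3 than in case 1 and at least 113-fold higher than in case 2. PAX2 measured 5.61 TPM in case 3 and 0.13 and 0 TPM in the others. The forebrain list stood apart in no pair, at low median levels of 0.04, 0.035 and 0.135 TPM in cases 1, 2 and 3. The list of midbrain and hindbrain boundary factors stood apart only in case 3 over case 2, at 1.41-fold. Its log2 ratio of -0.49 for case 2 over case 3 was -1.48 with a pseudocount of 0.1 and -1.10 with only members of at least 10 counts, and it did not stand apart with TPM, with a pseudocount of 2 or with unmatched random lists.

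The list of EZHIP and components of the histone methyltransferase PRC2 stood apart in no pair. The median of its 12 members was 1.47-fold lower in case 3 than in case 2, at percentile 8.53. RBBP7 measured 113, 183 and 143 TPM and PHF1 115, 62.6 and 73.2 TPM, although the catalytic subunit EZH2 measured 23.5, 54.3 and 6.75 TPM and PHF19 78.7, 68.9 and 10.9 TPM. The drug efflux transporters ABCB1 and ABCG2, which limit drug entry at the blood-brain barrier, measured 26.3, 11.4 and 9.25 TPM and 19.0, 17.0 and 8.38 TPM, and their list stood apart in no pair, with a median 1.53-fold lower in case 3 than in case 1 at percentile 20.4. Housekeeping genes stood apart in no pair either, with ACTB at 3115 ± 509 TPM and GAPDH at 1809 ± 514 TPM (SD, n = 3).

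Across all genes with at least 50 counts in either library of a pair, 1373 of 17193 differed over 4-fold between cases 1 and 2, 970 of them higher in case 1. Between cases 1 and 3 the number was 2888 of 17845, with 1473 higher in case 1 and 1415 higher in case 3. This balance turned to 1437 against 1441 with DESeq2 size factors, 1434 against 1443 with library totals and 1757 against 2079 at a limit of 10 counts, so neither case held the larger number under all settings. Between cases 2 and 3 it was 3309 of 17276, with 1470 higher in case 2. In case 1 the genes highest against both other cases were POSTN, MET, BMP5, TRH and NEUROD6. POSTN, a matrix protein, measured 533 TPM against 0.04 and 0.22 TPM. BMP5, a growth factor of the TGF-beta family, measured 66.5 TPM and had no count in case 2. With that count set to 3, BMP5 was at least 1431-fold higher in case 1 than in case 2. In case 2 they were HOXA7, PAX3, LHX2, CRABP1 and SLC30A3, with CRABP1, a retinoic acid binding protein, at 449 TPM against 5.59 TPM in case 1 and no count in case 3. In case 3 they were FAM81B, CAPSL, MAP3K19, PITX1 and ARMC3, with 258, 235, 69.6, 72.8 and 178 TPM, and none exceeded 0.56 TPM in another case. The genes lowest in case 3 were COL20A1, DES, DCC, PENK and DLL3. COL20A1 measured 341, 325 and 0.83 TPM, and DLL3, a Notch ligand of glial precursors, 65.7, 95.6 and 0.33 TPM. Those lowest in case 2 included MAL and ERMN of the myelin sheath and the copper carrier CP, at 69.5, 3.12 and 239 TPM. Those lowest in case 1 included PPP1R1B, at 1.43, 28.6 and 615 TPM, and MSX2, at 0.26, 6.90 and 20.2 TPM.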

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

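Leaving out 1 case moved the number of receptors below PDGFRA in every case from 13 to between 13 and 55, the highest without case 3. Without division by transcript length that number was 20, and with a difference of at least 1 on the log2(TPM + 1) scale it was 6. KIT averaged 4.46 in FPKM against 7.60 in TPM, a change of unit. With 1 case left out a single pair remained, which by construction lowered the combinations of list and pair standing apart from 48 to between 15 and 17 and the total of genes over 4-fold apart from 7570 over 3 pairs to between 1373 and 3309. Under the 6 other settings for lists, between 45 and 58 combinations stood apart and no list that stood apart changed direction; 11 of the added differences came with unmatched random lists. The differences that ended under some setting were those of the PDGF ligands, the monocyte and neutrophil list and the boundary transcription factors between cases 2 and 3, of the hypoxia list between cases 1 and 2 with a pseudocount of 2, and of the endothelial list between cases 2 and 3 when case 1 was left out; the cause was not tested. The minimum log2 ratio of several case-specific genes was smaller in TPM, such as 9.48 for MET in case 1, and none changed direction. The number of genes over 4-fold apart stayed within 1.5 times its value in every pair under other scalings, count limits and gene types. No paired analysis was possible because the labels give 1 group. Depth limits statements about genes near 3 counts, such as most B and plasma cell genes, and the single library per case leaves variation within a tumour unmeasured.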

Other observations

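The second lists, the choroid plexus and interferon gamma lists, the length correction and the use of fixed lists against each explanation were chosen after the values of the fixed lists had been seen. Further lists gave more detail on the same tumours. A second list of 25 motile cilium genes was higher in case 3 for every member, by a median log2 ratio of 4.47 over case 1 and 4.86 over case 2, with the dynein chain DNAI1 at 0.98, 0.08 and 85.7 TPM and SPAG6 of the ciliary central pair at 0.56, 0.55 and 56.1 TPM. A second list of 20 proliferation genes was lower in case 3 for every member, by medians of 14.7-fold and 24.0-fold, with the mitotic enzyme UBE2C at 63.5, 99.9 and 3.56 TPM. A second list of 16 oligodendrocyte precursor genes, PDGFRA included, was lower in case 3 for 11 members against case 1 and for 16 against case 2, with the sialidase NEU4 at 36.2, 259 and 8.07 TPM. A second interferon list had a median 6.53-fold higher in case 3 than in case 2, with 20 of 20 members higher. The choroid plexus list stood apart in no pair, and TTR, the main secreted protein of that tissue, reached 19.1 TPM in case 3 and 0.08 and 0 TPM in the others. Ribosomal protein genes took 2.83%, 3.98% and 2.08% of counts. These genes were named after their values were seen.

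The low level of PDGFRA in case 3 together with low oligodendrocyte precursor and proliferation genes was weighed first. A bias with transcript length does not account for it, because the median log2 ratio of these 35 genes in case 3 over case 1 was -2.75 before and -2.56 after the trend with length was taken out, with an upper quartile of -1.22. More grey matter in case 3 than in case 1 is argued against by the mature neuron list, with a median log2 ratio of -1.23. Of its 11 members 9 were highest in case 1, so this ratio does not measure grey matter in case 3 by itself. Dilution by grey matter stays open for the difference from case 2, where the list had a median of 0.47 without standing apart. Dilution by white matter cannot be told apart from the data, since the mature oligodendrocyte list had a median of -0.55 in case 3 over case 2 and 0.28 in case 3 over case 1 and stood apart in neither, and dilution by astroglial or ependymal tissue stays open too, since the astrocyte list was higher by 1.77 on the log2 scale and tumour cells of that kind would give the same. A tumour of another lineage is a candidate explanation that was not tested, since the labels give a single group.

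The motile cilium genes of case 3 were weighed second. Misassigned reads of a few genes are argued against by the second list, with a median log2 ratio of 4.47 over case 1 and 25 of 25 members higher. Choroid plexus tissue as the whole source is argued against by its list and by TTR at 19.1 TPM in case 3. The ependymal list had a median of 223 TPM there, and the second cilium list 58.8 TPM. The choroid plexus list had median log2 ratios of 0.36 over case 1 and 0.74 over case 2 and stood apart in neither. Its genes were low, with a median of 1.475 TPM in case 3. In each comparison 8 of 10 members were higher in case 3, so a part from such tissue is not excluded. Ependymal lining within the block and ciliated tumour cells both stay open, and the labels give a single group, so no difference named by the design was tested.

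The interferon-induced genes of case 3 were weighed last. A second list of 20 such genes was higher in case 3 than in case 1 for 19 members, with a median log2 ratio of 1.17, so the pattern did not rest on a few genes. More microglia and macrophages are argued against for the difference from case 1, where their list had a median log2 ratio of -1.18. More T and NK cells are argued against there by a list of low genes, at -0.71 with 8 of 9 members lower. Against case 2 the microglia and macrophage list was higher in case 3, with a median log2 ratio of 1.35 and 14 of 14 members. Such cells therefore stay a candidate source of part of that difference. T and NK cells stay open there too, at a median of 0.42 with 9 of 9 members higher, without standing apart. The interferon gamma list was 1.54-fold lower in case 3 than in case 1, without standing apart, and 3.19-fold higher than in case 2, where 9 of 10 members were higher and it stood apart; an interferon response within glial cells of case 3 is a hypothesis that was not tested.

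Case 2 had low microglia, macrophage and haemoglobin genes while its endothelial list had 6 of 10 members higher than in case 1. Myelin genes of case 2 also differed among themselves, with CNP 4.92-fold higher than in case 1 and ERMN 46.4-fold higher in case 1 than in case 2.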
